A study of Mus musculus with 8 samples.

How the data were processed

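Total RNA of 8 subcutaneous MC38 tumors was isolated with TRIzol and made into strand-specific TruSeq libraries, per the labels' protocols. The submitters' processing notes name FastQC, STAR 2.5, Cuffnorm, DESeq 1.22.1 and the genome build mm10, with no role or order. The authors' deposited table gives, for each gene, a log2 value per tumor, an FPKM value per tumor, group means, a log2 fold change, a p-value, an FDR and GO and KEGG terms. The test behind the p-value is not given in the sources used here. The table holds 752 genes and, checked on its values, every one has a p-value of at most 0.04995 and an absolute log2 fold change above 1. The largest FDR in the authors' deposited table is 1.00, 437 genes have an FDR above 0.5, and the FDR values, if adjusted by Benjamini-Hochberg, need at least 29423 genes, so the table is a selected part of a larger one.

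The deposited log2 values are log2 of a normalized count plus 1. For each tumor the normalized counts were whole multiples of one step, the value of 1 read, in 100% of the values above 0 at a tolerance of 0.1 read. The inverse of the step is the relative size factor, from 0.644 to 1.27. This recovers the reads of each listed gene but no library total, so the sequencing depth is unknown, and a value of 3 reads equals a normalized count of 2.37 to 4.66. The authors' log2 fold change is the mean log2 value of the F. nucleatum tumors minus that of the anti-PD-1 tumors. Deposited FPKM values are fragments per kilobase of transcript, scaled by library size. No gene changed direction between the log2 values and log2(FPKM + 1). Log2 differences are understated for genes with few reads because 1 is added to each value. The median gene of the table has a mean of 0.163 FPKM. All 752 gene IDs were found in GENCODE M21 on GRCm38, the same assembly as mm10, which gave the positions.

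Groups followed the labels. Replicate numbers are names given in accession order and pair no tumors. The labels give 1 tumor number per library, and separate mice are not stated for each. The limma and permutation p-values therefore measure the spread between these tumors. The authors' p-values and FDR need not do so. Krt6a, with 100% of its normalized counts in 1 tumor, had an authors' FDR of 4.51e-11 and an unadjusted limma p of 0.255. For Cxcl9 these were 0.934 and 0.00673. At least 90% of the normalized counts came from 1 tumor in 102 of the 114 higher genes with an authors' FDR under 0.05. The same held for 4 of the 47 lower ones. No pair of the 8 libraries agreed within sampling noise (smallest chi-square per degree of freedom 28.4). No sequencing batch is given in the labels.

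Because the table holds selected genes, the authors' deposited fold changes and FDR values are the account of which genes changed, a choice fixed before the data were examined together with 30 gene lists and the tests. SEs are those of a difference of 2 means of 4 log2 values. List members were counted by direction and tested with a two-sided Fisher's exact test against the other genes of the table, with Benjamini-Hochberg adjustment over the 10 lists with at least 5 genes there. For adjustment over the list alone, the authors' p-values were adjusted over all genes of the list with genes outside the table set to 1. List scores are means per tumor of centred log2(FPKM + 1), compared by a two-sided exact permutation test. GO and KEGG terms with 10 to 300 genes in the table were tested in the same way as lists, among annotated genes. The fit used limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM and an adjusted p under 0.05. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

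Named genes followed a fixed rule: the 8 higher and 8 lower genes with the largest change among limma calls without overlap between groups, which gave none since there were 0 calls; up to 4 genes per described list with the smallest limma p; and 15 genes fixed singly. Other names are said to be chosen after their values were seen.

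Settings listed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median centring, quantile normalization, limma without trend, limma with array weights, an exact rank-sum test, each tumor left out in turn, an adjusted p under 0.01, and terms of 5 to 500 genes. An estimated correlation was listed only for a set test that was not used. Settings added after seeing the data were the deposited log2 values in place of FPKM, voom on the recovered reads, a filter at 1 FPKM for the lists, and leaving out tumors 36 and 37 together. On simulated values with the typical spread of the 149 genes, limma recovered 90% of genes changed 4-fold and 100% of genes changed 8-fold, with 1 of 109 unchanged genes called. On simulated log2 normalized counts with the typical spread of all 752 genes it recovered 21% and 74%, with 2 of 552 unchanged genes called, so most simulated 4-fold changes were missed there. Genes carried by 1 tumor spread far more than that. In both simulations every gene had the same spread and varied independently. Real genes differ in spread and move together, so the recovered shares do not measure the power of the real fits. In a simulation of 29423 unchanged genes with the spreads of the table, selection at a p under 0.05 and a log2 difference above 1 kept 1488 genes, of which limma called 80.4% when they were tested alone and 0 before selection. The simulated selection used limma, while the authors' test is not known. On the real table limma without a filter called 0 of 752 genes, so 80.4% is no estimate for it. Selection on the same tumors is why adjusted p-values within the table are not independent evidence. Fisher's test gave a p under 0.05 for 3% of lists when directions were shuffled over single genes. Such shuffling removes the shared movement of list genes, so this share gives no error rate for lists whose genes move together.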

Results

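Bulk RNA was sequenced from 8 subcutaneous MC38 tumors of germ-free C57BL/6 mice, grown from a mouse colon adenocarcinoma cell line and dissected on day 23. In 4 of them (tumors 11, 17, 18 and 19, replicates 1 to 4) the mice received an antibody against PD-1, the inhibitory receptor of activated T cells. In the other 4 (tumors 36, 37, 39 and 40, replicates 1 to 4) the mice received the same antibody and Fusobacterium nucleatum, an anaerobic bacterium of the mouth and gut, by gavage. The comparison asks how the bacterium alters the tumor transcriptome under anti-PD-1 therapy. The authors' deposited table holds 752 genes, all with an unadjusted p under 0.05 and an absolute log2 difference above 1 in that comparison. Recovered reads in these genes ranged from 97511 to 308139 per tumor, and the relative size factors from 0.644 to 1.27. Size factors were 0.986 ± 0.258 with anti-PD-1 alone and 1.07 ± 0.199 with F. nucleatum (mean ± SD, n = 4 each, exact permutation p = 0.657).

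Those genes of the antigen presentation, interferon response and lymphocyte lists that the authors' deposited table holds had lower means in the F. nucleatum group, and those of the skeletal muscle, skin and red blood cell lists had higher ones. The table holds part of each list, from 8 of 36 type I interferon genes to 23 of 30 skin genes among these, and values of the other members were not analysed here. No score per tumor of these lists passed after adjustment in the main setting. Some passed with quantile normalization within the selected genes, or with some single tumors left out. H2-K1, a classical MHC class I heavy chain, fell from 59.4 ± 4.19 to 29.5 ± 11.0 FPKM (mean ± SD, n = 4 each), and Pdcd1, which encodes PD-1 itself, fell from 0.821 ± 0.0736 to 0.162 ± 0.113 FPKM. The skin genes were high in tumor 37 and the muscle genes in tumor 36, and the immune list scores of the group were highest in tumor 36. In the authors' deposited table, 399 genes were higher with F. nucleatum and 353 were lower. A false discovery rate (FDR) under 0.05 was reached there by 114 higher and 47 lower genes, and 591 genes had a larger FDR. Here "rose" and "fell" are used of single genes with an FDR under 0.05 in that table. These words do not state that a change was shared by the tumors of a group.

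The higher and lower genes differed in how many tumors carried them. At least 90% of the normalized counts came from 1 tumor in 160 of the 399 higher genes and in 11 of the 353 lower genes (Fisher's exact test, p = 2.0e-38). Tumor 37 was that tumor for 123 of the higher genes and tumor 36 for 34. The test counts genes as independent although most of these rest on the same tumors, so its p-value does not measure a difference between groups of tumors. Among genes with an FDR under 0.05 in the authors' deposited table, 102 of the 114 higher and 4 of the 47 lower genes rested on 1 tumor in this way. The values of the 4 and 4 tumors did not overlap in 93 lower genes (26.3%) and in 54 higher genes (13.5%), where chance gives 2.86% for a gene that was not selected. The 90% mark was chosen after the values were seen.

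**Figure D1:**
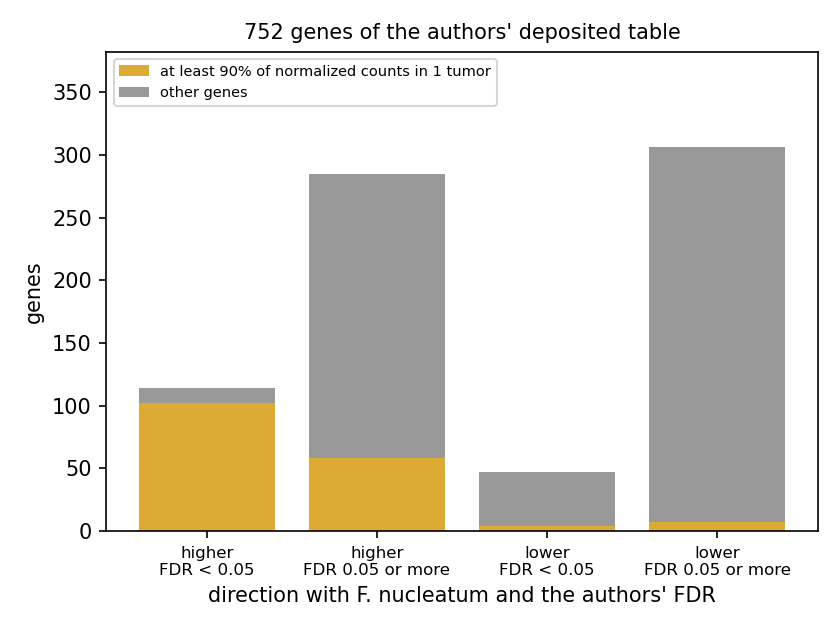
Number of genes (vertical axis) in the authors' deposited table by direction with F. nucleatum and by the authors' FDR, with genes that have at least 90% of their normalized counts in 1 tumor marked in yellow. Of the 114 higher genes with an FDR under 0.05, 102 are marked, against 4 of the 47 lower ones.

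Genes of antigen presentation were lower with F. nucleatum in both MHC classes. Of 22 class I genes listed, 7 were in the table and all 7 were lower, with a median log2 difference of -1.22, and of 14 class II genes listed, 8 were in the table, all lower, with a median of -2.02. H2-K1 (chromosome 17, 33996017 to 34000347, GRCm38) differed by a log2 value of -1.07 ± 0.244 (SE), H2-Q4 by -1.45 ± 0.372 and H2-Q6 by -1.62 ± 0.396, and these 3 genes fell. The class II chains H2-Ab1 (chromosome 17, 34257689 to 34269419) and H2-Eb1 (chromosome 17, 34305867 to 34316674) fell by 2.06 and 2.17 on the log2 scale, from 30.1 ± 12.9 to 7.61 ± 4.79 FPKM and from 25.9 ± 10.9 to 6.35 ± 4.68 FPKM (mean ± SD, n = 4 each). Cd74, the invariant chain of class II, had 95.7 ± 50.02 FPKM with anti-PD-1 alone and 25.0 ± 16.6 FPKM with F. nucleatum. Its FDR in the authors' deposited table was 0.143, and that of H2-Aa was 0.234. An FDR under 0.05 was held there by 4 class I and 5 class II genes, and 7 and 8 had one when adjusted over the list alone. H2-Q4, H2-Q6 and H2-Q7 are close copies whose reads cannot be assigned with certainty.

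The interferon genes went the same way. The interferon-gamma list, which holds guanylate-binding proteins (Gbp) and other targets of this T cell cytokine, had 19 of its 30 genes in the table and all 19 were lower (median log2 difference -2.12). The values of the 4 and 4 tumors did not overlap in 2 of these 19 genes. Cxcl9, a chemokine that attracts activated T cells, had log2 normalized counts of 11.19 ± 1.31 with anti-PD-1 alone and 7.64 ± 2.19 with F. nucleatum (mean ± SD, n = 4 each), and Cxcl10 had 10.28 ± 0.95 and 8.97 ± 0.92. Their FDR values in the authors' deposited table were 0.934 and 0.991. The interferon-induced GTPases Tgtp1 and Tgtp2, near-identical neighbours on chromosome 11 whose counts are uncertain for that reason, differed by -2.95 ± 0.963 and -2.81 ± 0.969 (SE), and Gbp3 by -2.17 ± 0.790. Of the 19 genes, 2 had an FDR under 0.05 in the authors' deposited table, namely Ciita, the master regulator of MHC class II, and Gbp8, and 13 had one when adjusted over the list alone. Of 36 type I interferon-stimulated genes listed, 8 were in the table, all lower (median -1.25), and Zbp1, a sensor of nucleic acids, fell from 2.39 ± 0.430 to 0.854 ± 0.391 FPKM (mean ± SD, n = 4 each). Zbp1 and Oas3 were the 2 with an FDR under 0.05 in that table, and 2 genes had one when adjusted over the list alone. The values of the 4 and 4 tumors did not overlap in 1 of the 8 genes. Ciita, Gbp8 and Oas3 were named after their values were seen.

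Lymphocyte genes were lower as well. The table held 14 of 26 T cell genes and 17 of 28 cytotoxic lymphocyte genes, all lower, with median log2 differences of -1.78 and -2.46. Gzmb (chromosome 14, 56258838 to 56262260), a protease of cytotoxic granules, fell from 3.39 ± 2.06 to 0.792 ± 0.528 FPKM (mean ± SD, n = 4 each). Cd8a, the co-receptor of cytotoxic T cells, fell from 0.534 ± 0.304 to 0.0845 ± 0.0788 FPKM, and Ccl5, a chemokine made by activated T cells, from a log2 normalized count of 7.80 ± 0.864 to 5.70 ± 0.982. Gzma and Nkg7 differed by -2.93 ± 1.42 and -2.30 ± 0.814 (SE), and neither reached an FDR under 0.05 in the authors' deposited table. That table gave such an FDR to 2 T cell genes (Cd8a and Lck) and to 4 cytotoxic genes (Cd8a, Gzmk, Gzmb and Ccl5), and 12 and 15 genes had one when adjusted over the list alone. Lck and Gzmk were named after their values were seen.

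Checkpoint, myeloid and chemokine genes of the table were also lower. Pdcd1 (chromosome 1, 94038305 to 94052553) differed by -2.44 ± 0.414 (SE) and Cd274, which encodes the PD-1 ligand PD-L1, by -1.23 ± 0.536. Their FDR values in the authors' deposited table were 6.2e-05 and 0.712. Among 4 of 25 neutrophil genes in the table, all lower, Lcn2 fell by 1.64 and Il1r2 by 1.06 on the log2 scale. The 6 of 35 chemokine genes in the table were all lower (median -1.70), of which Ccl5 had an FDR under 0.05 in that table and 3 genes had one when adjusted over the list alone. The table held 3 of 19 dendritic cell genes, 3 of 12 regulatory T cell genes and 2 of 26 inflammatory cytokine genes, all lower, and none of these reached an FDR under 0.05 there.

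**Figure D2:**
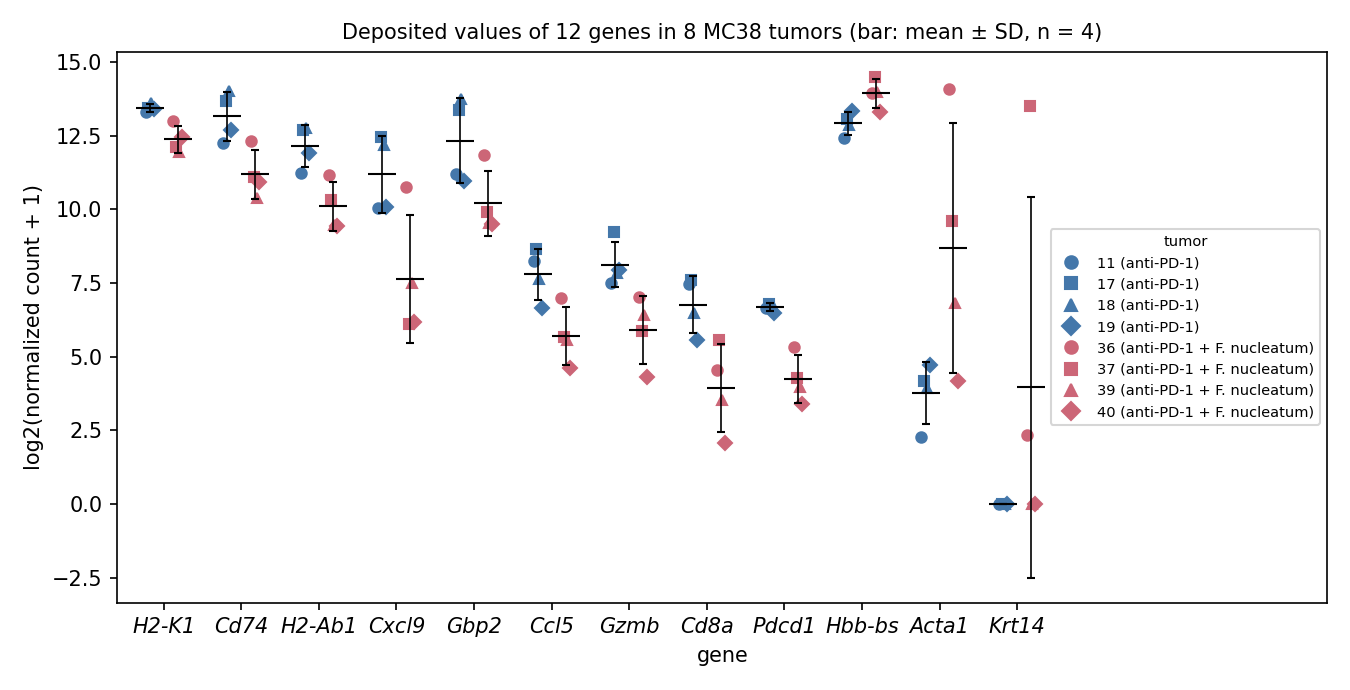
Log2(normalized count + 1) (vertical axis) of 12 genes in each tumor, blue for anti-PD-1 and red for anti-PD-1 + F. nucleatum, with the group mean ± SD (n = 4) in black. H2-K1 and Pdcd1 are lower in all 4 F. nucleatum tumors, Krt14 is at 0 in the anti-PD-1 tumors and high in tumor 37, and Acta1 is highest in tumor 36.

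Genes of skeletal muscle were higher with F. nucleatum, and all 26 of the 34 listed muscle genes found in the table had their highest value in tumor 36. Acta1 (chromosome 8, 123891769 to 123894751), the actin of skeletal muscle, rose by a log2 value of 4.90 ± 2.19 (SE), from 0.146 ± 0.0883 to 48.4 ± 90.7 FPKM (mean ± SD, n = 4 each), and 94.7% of its normalized counts came from tumor 36. Tnnt3 and Mylpf had log2 differences of 2.60 ± 1.60 and 1.97 ± 1.07 and FDR values of 0.0638 and 0.202 in the authors' deposited table. An FDR under 0.05 was held there by 8 muscle genes, and 25 had one when adjusted over the list alone. The median log2 difference of the muscle genes was 3.19 with all tumors and 0.65 without tumors 36 and 37.

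Genes of keratinocytes and skin were higher in tumor 37. The table held 23 of 30 listed skin genes, and all 23 had their highest value there. Krt14 (chromosome 11, 100203162 to 100207548), a keratin of basal keratinocytes, and Krt6a, a keratin of wounded epidermis with the close copy Krt6b, were listed at 0 in all 4 anti-PD-1 tumors. Tumor 37 held 99.97% of the normalized counts of Krt14 and 100% of those of Krt6a. The list had 15 genes with an FDR under 0.05 in the authors' deposited table, and 21 when adjusted over the list alone. Without tumor 37 the median log2 difference of the 23 genes was 0, and none of them kept a difference above 1.

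Genes of red blood cells were higher too. Of 7 in the table, from a list of 16, 6 rose, with a median log2 difference of 1.07 over the 7. Hbb-bs, an adult beta-globin, rose from 162.3 ± 40.1 to 333.3 ± 109.8 FPKM and Hba-a2, an adult alpha-globin, from 129.7 ± 31.4 to 281.7 ± 97.9 FPKM (mean ± SD, n = 4 each). The globin copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, share sequence and are uncertain as single genes. All 7 had an FDR under 0.05 in the authors' deposited table when adjusted over the list alone. All 7 also had their highest value in tumor 37, which held 23.9% of the normalized counts of Hbb-bs. Without tumor 37 the median log2 difference of the 7 genes was 0.87 and 2 kept a difference above 1, and without tumors 36 and 37 it was 0.69 and 1 kept one. All 7 stayed higher in both cases. The values of the 4 and 4 tumors did not overlap in 1 of the 7 genes. On log2(FPKM + 1) the list score of F. nucleatum tumor 40 (-0.25) lay within the range of the anti-PD-1 tumors (-0.76 to -0.17).

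**Figure D3:**
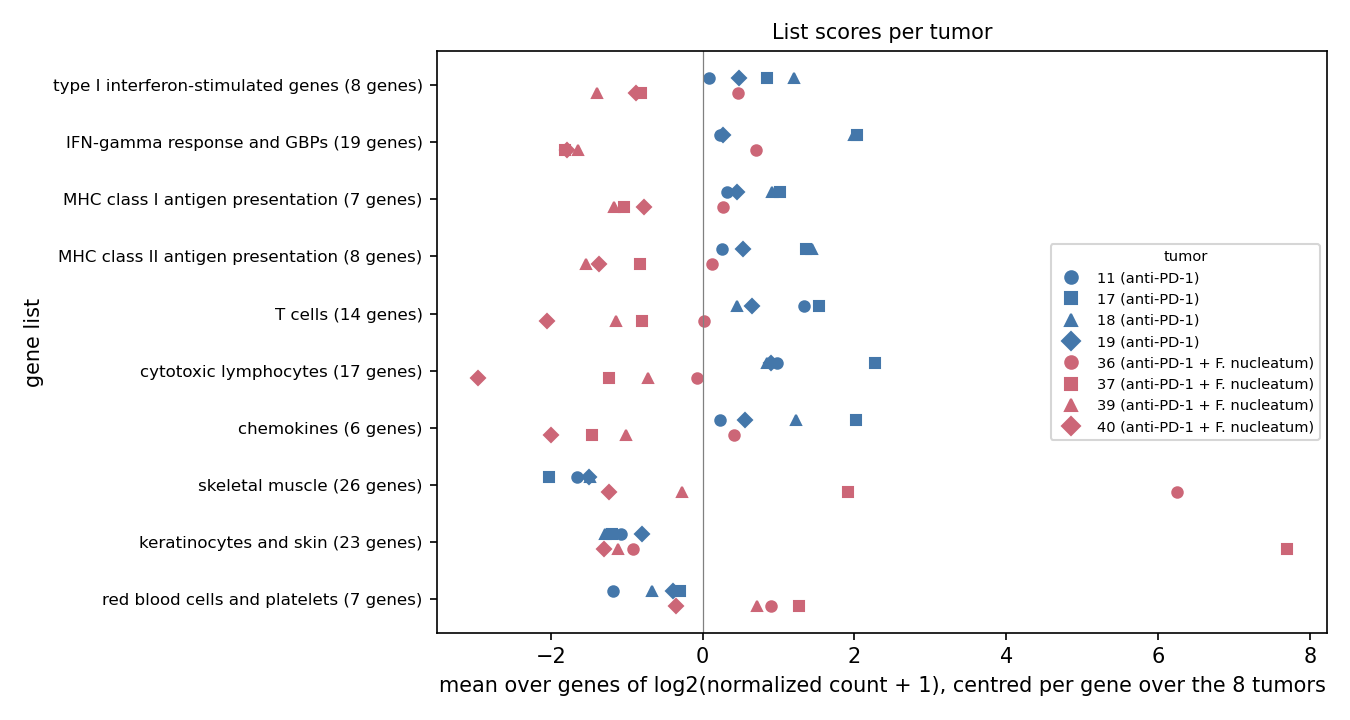
List score per tumor (horizontal axis, mean over list genes of log2(normalized count + 1) centred per gene) for the 10 lists with at least 5 genes in the table, blue for anti-PD-1 and red for anti-PD-1 + F. nucleatum. Tumor 37 stands at 7.70 for skin genes, tumor 36 at 6.24 for muscle genes, and tumor 36 is the highest of its group in the 7 immune lists.

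The 10 lists with at least 5 genes in the table were tested for direction against its other genes (two-sided Fisher's exact test). Each of the 10 passed, with adjusted p from 4.9e-07 for skeletal muscle to 0.0164 for red blood cells. The genes had been selected on these same tumors, so these tests and the counts adjusted over the list alone are not independent evidence of a direction. Among genes with a mean of at least 5 FPKM none of the 7 lists left passed (adjusted p from 0.134 to 0.506). The lists then held 1 to 5 genes each, all in their former direction. So few genes limit this test, and its result shows no change of direction. At 1 FPKM, a filter chosen after seeing the data, both MHC classes (0.0595), type I interferon and chemokines (0.0844) and T cells (1) did not pass. The genes left in these lists were all still lower, and the T cell list held 1 gene. Without tumors 36 and 37, also chosen after seeing the data, MHC class I (0.0591), chemokines (0.0967) and skin (0.712) did not pass. The 7 MHC class I and 6 chemokine genes all stayed lower there, with median log2 differences of -1.54 and -2.39. The test sets a list against the other genes. Of these, 16 muscle genes were then higher and 8 lower, and 2 skin genes higher and 5 lower. With quantile normalization red blood cells (0.127) did not pass, with 6 genes higher and Hbb-bs lower. Scores per tumor on log2(FPKM + 1) were 0.50 ± 0.25 with anti-PD-1 alone and -0.50 ± 0.47 with F. nucleatum for MHC class I (mean ± SD, n = 4 each, exact permutation p = 0.0286, the smallest that 70 arrangements allow). For class II they were 0.66 ± 0.46 and -0.66 ± 0.54 at the same p. Scores for T cells, cytotoxic lymphocytes and chemokines had that p too, and the score differences of type I interferon, interferon-gamma, muscle, red blood cell and skin genes had an exact permutation p of 0.0571, 0.0857, 0.0571, 0.0571 and 0.343. After adjustment over the 10 lists no score passed, the smallest adjusted p being 0.0571. The exact permutation p cannot fall below 0.0286, so a score passes only where enough of the 10 lists reach that p together. The lists are not separate results, since some share genes. Chemokines shared 3 genes with interferon-gamma and 2 with cytotoxic lymphocytes. T cells shared 2 with cytotoxic lymphocytes, and interferon-gamma shared 1 with MHC class II. Without tumor 36 the scores of type I interferon, both MHC classes, T cells, cytotoxic lymphocytes and chemokines passed (adjusted p = 0.0476 by exact permutation). Of these, all but type I interferon had the same unadjusted p with all tumors. Without tumor 40 those of both MHC classes, cytotoxic lymphocytes, chemokines, muscle and red blood cells passed at the same value. With quantile normalization the scores of type I interferon, interferon-gamma, both MHC classes, T cells, chemokines, muscle and red blood cells passed (adjusted p = 0.0357 by exact permutation). It gives every tumor the same set of values, here within the 752 selected genes alone. These genes were chosen to differ, so its premise of like distributions need not hold. Genes at equal values, such as 0, were ranked by their order in the table. These passes carry that limit. The muscle score difference was 0.91 with all tumors and 0.24 without tumor 36, and that of skin was 0.71 and, without tumor 37, 0.0064. Without tumor 37 the direction test of the skin list had an adjusted p of 1 (4 genes higher, 4 lower). With each tumor centred to the same median the T cell list turned to a higher score (0.16, adjusted p = 0.486 by exact permutation), with 11 genes higher and 3 lower. This scaling adds 0.45 to every difference on log2(FPKM + 1), where the T cell score differed by -0.30 and 1 of its 14 genes had a mean of at least 1 FPKM, so small differences of low genes turn by arithmetic. Without centring the T cell score differed by -1.03 at a pseudocount of 0.1 and by -1.99 on log2 normalized counts. The cytotoxic list then had 12 genes lower and 5 higher and a score difference of -0.24 in place of -0.69 (adjusted p = 0.317), interferon-gamma had 16 lower and 3 higher (-0.65 in place of -1.11), and type I interferon 7 lower and 1 higher (-0.20 in place of -0.65). Of the MHC genes all 7 of class I stayed lower (score difference -0.55) and 7 of the 8 of class II. The direction test of the red blood cell list had an adjusted p of 0.679 in that scaling.

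No gene of 14 other lists was in the table. These lists cover the cGAS-STING pathway, B cells, macrophages, the HIF-1 response, glycolysis, the tricarboxylic acid cycle and succinate, oxidative phosphorylation, polycomb, the cell cycle, fibroblasts and matrix, endothelium, adipocytes, immediate early genes, and neurons and Schwann cells, 348 list entries in all. Of 15 genes fixed singly, 7 were in the table, all lower, and the other 8 (Ifnb1, Cgas, Sting1, Prf1, Ifng, Sucnr1, Hif1a and Ezh2) were outside it. Outside the table a gene's values were not analysed here, so its absence gives no bound on its change. The lists also do not hold every gene of their cell type or pathway. Aif1 and C5ar1, genes of myeloid cells, and Hif3a, a gene of the HIF family, were in the table but not on these lists. They differed by log2 values of -1.01, -1.16 and -2.85, none with an FDR under 0.05 in the authors' deposited table, and were named after their values were seen. Immunoglobulin genes, which the B cell list does not hold, were in the table with 2 constant and 3 variable gene segments, all lower. Igha differed by a log2 value of -3.04 ± 0.900 (SE), with 5 to 39 recovered reads per tumor with anti-PD-1 alone and 0 to 9 with F. nucleatum. Ighg2c differed by -1.77 ± 1.19, with 90.9% of its normalized counts in tumor 11, and Fcrl5, a receptor of B cells, by -3.73 ± 1.42, with 0 reads in all 4 F. nucleatum tumors and in tumor 19. Their FDR values in the authors' deposited table were 0.267, 0.745 and 0.428. Immunoglobulin segments share sequence and are uncertain as single genes, and these 3 genes were named after their values were seen. Of 25 genes on the epithelial and Wnt list, 3 were in the table and higher, among them Epcam with 98.7% of its normalized counts in 1 tumor.

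The deposited gene annotations gave immune, skin and muscle terms. Of 585 GO and KEGG terms tested for direction, 97 leaned to the lower and 89 to the higher genes at an adjusted p under 0.05 (Fisher's exact test). Without tumors 36 and 37, a setting chosen after seeing the data, 43 leaned to the lower and 62 to the higher genes. Immune system process held 104 lower and 13 higher genes (adjusted p = 1.3e-20), and adaptive immune response held 35 lower and 0 higher genes. The KEGG pathway antigen processing and presentation held 18 lower and 0 higher genes (adjusted p = 0.00459), and natural killer cell mediated cytotoxicity also held 18 and 0. On the higher side stood intermediate filament, with 49 higher and 1 lower gene (adjusted p = 2.8e-12), myofibril, with 37 and 1, and keratinization, with 14 and 0. All 17 KEGG pathways that passed leaned to the lower genes. The genes had been selected on these same tumors and were counted as independent, so the term tests are not independent evidence of a direction. The listed skin and muscle genes had their highest values in tumors 37 and 36, and the share of these tumors was not counted per term.

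A fit of the FPKM values within the selected table gave no call. Of the 149 genes with a mean of at least 1 FPKM (62 higher, 87 lower), limma called 0 at an adjusted p under 0.05, the smallest adjusted p being 0.0664, and 73 had an unadjusted p under 0.05, 17 higher and 56 lower. The exact rank-sum permutation test also called 0, with 32 genes under 0.05 unadjusted where 86 at its smallest p would be needed for any call, and so did voom on the recovered reads of all 752 genes, with 258. Leaving out tumor 36, replicate 1 of the F. nucleatum group, moved the limma count to 57 lower and 3 higher genes, and array weights moved it to 75 lower and 13 higher. With each tumor centred to the same median, 8 higher and 5 lower genes were called, a split that goes with a shift of -0.45 between the group medians of log2(FPKM + 1). Any such count is taken within genes chosen on these tumors.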

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

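The Dixon comparisons and the exact permutation test of the list scores were fixed beforehand, and the other tests in this part were chosen after the results were seen, as was the use of the list scores to weigh chance. The Dixon comparisons asked, for list scores, named genes and size factors, whether 1 tumor lay far from the other 3 of its group. They covered 108 groups of 4 values, of which 8 stood out where chance gives about 1 in 20, or 5.4.

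The skin list score of tumor 37 on log2(FPKM + 1) was 2.45, against -0.37 to -0.32 in the other F. nucleatum tumors, and 2 skin genes stood out with it, Krt6a at a log2 normalized count of 12.50 against 0 in the others and Krt10 at 11.53 against 5.47 to 6.37. Among higher epidermal and keratin genes outside the fixed list, 87.7% (50 of 57) had at least 90% of their normalized counts in tumor 37, against 123 of all 399 higher genes. Skin carried along with that tumor may explain this share, which the selection of the table on these tumors also favours. An effect of F. nucleatum shared by its 4 tumors is argued against by the skin score of the other 3 tumors, which lay at -0.026 ± 0.193 (SD, n = 3) from the anti-PD-1 mean when scored on log2 normalized counts. A change of the tumor cells of tumor 37 towards skin was not tested.

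The muscle genes of tumors 36 and 37 form another such pattern. The listed muscle genes summed to 73262 normalized counts in tumor 36 and 3740 in tumor 37, against 416 to 950 in the other 6. In 76.9% of the 26 muscle genes (20 genes) tumor 36 was highest and tumor 37 second, short of the share set for muscle tissue carried with both tumors, so this source may hold for tumor 36 and stays open for tumor 37. Scored on log2 normalized counts, the muscle genes of tumors 39 and 40 lay 0.91 ± 0.680 (SD, n = 2) above the anti-PD-1 mean, so a smaller rise shared by the group cannot be told apart from their spread. On log2(FPKM + 1), the scale of the list scores above, the gap was 0.056 ± 0.051, but all 26 genes had a mean under 1 FPKM in the 6 tumors other than 36 and 37 (median 0.0284 FPKM), where adding 1 hides most of a change.

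The lower immune genes form the last pattern. Tumor 36 stood apart in its group at an interferon-gamma score of 0.29 against -0.88 to -0.78, at 9.69 against 7.32 to 7.60 for Gbp3 and at 9.23 against 7.48 to 7.68 for Oas1a (log2 normalized counts). Its interferon-gamma score lay above those of anti-PD-1 tumors 11 (0.012) and 19 (-0.052) and below those of tumors 17 (1.12) and 18 (1.13). Its type I interferon score of 0.234 lay between those of tumors 11 (0.0034) and 19 (0.237), with tumors 17 (0.418) and 18 (0.649) higher. Dilution by skin and muscle RNA would make tumors 36 and 37 the lowest, but without them the median log2 difference of the 71 immune list genes was -2.33, against -1.86 with all tumors, and 68 of the 71 were lower still. Variation in immune content that fell along the groups by chance stays open, since the smallest adjusted p of the list scores was 0.0571 in the main setting, at the smallest raw p the design allows. At the same raw p it was 0.0357 with quantile normalization and 0.0476 without tumor 36 (exact permutation). The adjusted p thus depends on how many lists reach that raw p, and this test cannot decide the question. An effect of F. nucleatum on immune content remains a hypothesis beside it. No group here received another bacterium, so an effect of this species cannot be told apart from one of any bacterium in germ-free mice.

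The cytotoxic score of tumor 17 was 0.92, against 0.12 to 0.18 in the other anti-PD-1 tumors. The skin score of tumor 19 was -0.32, against -0.37 to -0.36 in the other anti-PD-1 tumors.

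Other splits of the 8 tumors were set beside the real one on the limma count. The real split gave 0 genes, so all 35 splits give as many whatever the data, and this count says nothing about chance. Of the 34 other splits 1 called any gene. That split, tumors 11, 37, 39 and 40 against 17, 18, 19 and 36, gave 37 genes, and whether a structure of the tumors outside their groups lies behind it was not tested. Of these 37 genes, 18 were in the immune lists and 0 in the skin or muscle lists, and all 37 were lower with F. nucleatum in the authors' deposited table. Among all 149 genes tested, 42 were in the immune lists and 87 were lower.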

How the results depend on the processing

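Settings without tumors 36 and 37, the filter at 1 FPKM for lists, the deposited log2 values and voom were chosen after seeing the data; the others were planned. The main limma counts were 0 higher and 0 lower genes. They stayed at 0 and 0 without a filter, with quantile normalization, without the trend, with the deposited log2 values and with voom. An adjusted p under 0.01 (smallest 0.0664) and the exact rank-sum test (32 genes at its smallest p, 86 needed) also gave 0, which says nothing about stability. They were 2 and 17 with a pseudocount of 0.1, 6 and 11 at 5 FPKM (35 genes tested), 8 and 5 with median centring, 13 and 75 with array weights (0.152 for tumor 36, 0.221 for tumor 37, where the estimate stopped before it converged) and 5 and 27 without tumors 36 and 37. Leaving out 1 tumor gave 0 to 3 higher and 0 to 57 lower genes, the latter without tumor 36. Genes with a log2 difference above 1 numbered 399 higher, 256 to 392 with 1 tumor left out (256 without tumor 37) and 193 without tumors 36 and 37, where 24 turned, and 353 lower, 315 to 348 with 1 left out and 336 without both, where 0 turned. The cause was not tested beyond the single-tumor shares.

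The direction tests of the lists lost genes with a filter. At 5 FPKM the adjusted p was 0.161 for interferon-gamma and MHC class II, 0.506 for MHC class I, 0.362 for chemokines, 0.268 for muscle, 0.467 for skin and 0.134 for red blood cells, and no type I interferon, T cell or cytotoxic gene was left. At 1 FPKM it was 0.0844 for type I interferon and chemokines, 0.0595 for both MHC classes and 1 for T cells. At both filters every gene left kept its direction. The lists held 1 to 5 genes each at 5 FPKM, and the T cell list 1 gene at 1 FPKM. Without tumors 36 and 37 the adjusted p was 0.0591 for MHC class I, 0.0967 for chemokines and 0.712 for skin, which turned. The MHC class I and chemokine genes all stayed lower there. With 1 tumor left out the skin value ran from 1.4e-06 to 1, the latter without tumor 37, where 4 genes were higher and 4 lower. Median centring adds 0.45 to every difference on log2(FPKM + 1), so lower genes that differed by less had to turn, which says nothing of their fall on other scales. The T cell list (0.719) and its score (0.16) turned in this way, and red blood cells had 0.679. Scores under it were -0.20 for type I interferon, -0.65 for interferon-gamma, -0.55 for MHC class I, -0.86 for class II, -0.24 for cytotoxic genes, -0.69 for chemokines, 1.37 for muscle, 1.16 for skin and 1.27 for red blood cells, and 5 of 17 cytotoxic genes, 3 of 19 interferon-gamma genes and 1 each of the type I interferon, class II and chemokine genes turned higher. Quantile normalization gave 0.127 for red blood cells, with 6 genes higher and Hbb-bs lower. No filter is how the lists were counted.

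No list score passed in the main setting, nor at a pseudocount of 0.1 or on log2 normalized counts, which gave larger differences: -1.17 and -1.31 for type I interferon, -1.83 and -2.26 for interferon-gamma, -1.31 and -1.35 for MHC class I, -1.67 and -1.80 for class II, -1.03 and -1.99 for T cells, -1.63 and -2.50 for cytotoxic genes, -1.63 and -2.02 for chemokines, 1.91 and 3.33 for muscle, 1.33 and 2.18 for skin and 1.09 and 1.27 for red blood cells. With quantile normalization these passed: -0.45 for type I interferon, -0.94 for interferon-gamma, -0.71 for MHC class I, -1.14 for class II, -0.31 for T cells, -0.95 for chemokines, 0.79 for muscle and 0.41 for red blood cells (adjusted p = 0.0357 by exact permutation). These passes rest on ranks within genes selected to differ, where the premise of like distributions need not hold. With 1 tumor left out scores ranged from -0.84 to -0.55 for type I interferon, -1.39 to -0.91 for interferon-gamma, -1.23 to -0.89 for MHC class I, -1.57 to -1.18 for class II, -0.35 to -0.24 for T cells, -0.77 to -0.50 for cytotoxic genes, -1.38 to -0.92 for chemokines, 0.24 to 1.21 for muscle, 0.0064 (without tumor 37) to 0.948 for skin and 0.68 to 1.03 for red blood cells. Type I interferon, MHC, T cell, cytotoxic and chemokine scores passed without tumor 36, where interferon-gamma, muscle and red blood cells had 0.0635 and skin 0.257, and MHC, cytotoxic, chemokine, muscle and red blood cell scores passed without tumor 40 (adjusted p = 0.0476 by exact permutation). Each score that passed had the smallest unadjusted p the test allows, so passing turned on how many lists reached it. The skin score was -0.0086 without tumors 36 and 37. Terms numbered 89 higher and 97 lower, 102 and 112 at 5 to 500 genes, and 62 and 43 without tumors 36 and 37. Among named genes Atp2a1 (-0.20) and Sfn (-0.28) turned without those tumors and Hbb-bs (-0.026) with quantile normalization. A gene that stays among the highest ranks gets nearly the same value in every tumor under that normalization. Hbb-bs averaged 248 FPKM, so its turn says little of its change on other scales. Krt6a came to 0 without tumor 37, Krt6a and Krt14 came to 0 without tumors 36 and 37, and the other 553 alternative values kept their direction. The library totals are unknown, so low genes are limited by reads that cannot be stated as a share of a library.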

Other observations

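Genes outside the fixed lists, named after their values were seen, extend the account of the lower side. Sh2d2a, an adaptor of activated T cells, differed by a log2 value of -2.79 ± 0.430 (SE), Cd226, an activating receptor of T and natural killer cells, by -3.70 ± 0.772, and Cxcr6, a chemokine receptor of tissue T cells, by -1.92 ± 0.354. Their FDR values in the authors' deposited table were 1.1e-07, 2.2e-05 and 0.00125, and in each the 4 and 4 tumors did not overlap. Slc7a11, the cystine transporter, differed by -1.07 ± 0.362 and Saa3, an acute phase protein, by -1.65 ± 0.503, each with an FDR under 0.05 there. Gpm6b, a membrane glycoprotein best known from the nervous system, differed by -1.47 ± 0.294 with no overlap.

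On the higher side, few genes stood outside the skin, muscle and blood groups at an FDR under 0.05 without resting on 1 tumor. Napg, a protein of vesicle fusion, differed by 1.43 ± 0.422 (SE) and Btbd6 by 1.43 ± 0.494. Their FDR values in the authors' deposited table were 8.9e-05 and 0.0118. Efemp1, a matrix protein, had 13.8 FPKM over all tumors and a difference of 1.07 ± 0.406, its groups did not overlap, and its FDR was 0.0691 in that table. Hair follicle keratins were among the genes carried by tumor 37, with Krt25 and Krt71 at 100% of their normalized counts there.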
